A study of Homo sapiens with 8 samples.

How the data were processed

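RNA from HCT116 cells was sequenced after TRIzol extraction and preparation with a stranded TruSeq mRNA kit, per the labels' protocols. The labels give 4 groups of 2 libraries each, WT and DPF2 R350H cells, both untreated and after 24 h in 0.5 µM doxorubicin, and every library was mapped to its group from its label. The labels do not say whether the 2 libraries of a group came from separate cultures or how many edited clones were used, so p-values measure only the spread between these samples, which may be technical, and the edit cannot be separated from any other difference between the 2 lines.

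The authors deposited 1 table of counts per library, with whole-number read-pair counts per gene. Per the file headers, featureCounts 2.0.1 assigned fragments to exons of GENCODE release 34 at a minimum mapping quality of 10. The strand setting was 1 in untreated WT replicate 1 and in untreated R350H replicate 2 and 2 in the other 6 libraries, per the file headers. Per the submitters' processing notes, the build was hg38 and the tools were FastQC 0.11.4, Trim Galore 0.6.10, STAR 2.7.5a, featureCounts 1.5.0-p1 (a version that differs from the headers) and DESeq2 1.36.0. The authors also deposited TPM values of 202 genes in the 8 libraries. How these TPM values were made and how the 202 genes were chosen is not given in the sources used here. Their levels differ from TPM computed from the deposited counts and exon lengths, so they were compared only between libraries.

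Of 60669 genes in the count tables, 42052 had a symbol in the gene name table. Total counts ran from 28111673 in untreated WT replicate 2 to 33727374 in untreated WT replicate 1. Genes with low counts were removed by filterByExpr on the 4 groups, which kept 17868 genes holding 99.9% of the counts, 15814 of them with a symbol. The 2 libraries of each group differed by more than sampling noise, with a chi-square per gene of 8.62 in untreated WT, 8.15 in treated WT, 3.51 in untreated R350H and 2.00 in treated R350H, and none was a copy of another. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, 1 mean per group over all 8 libraries, 4 residual degrees of freedom, two-sided test, Benjamini-Hochberg adjusted p under 0.05). The biological coefficient of variation was 5.35%. The 5 contrasts were doxorubicin in WT, doxorubicin in R350H, R350H against WT untreated, R350H against WT with doxorubicin, and the difference between the 2 doxorubicin responses. CPM values use TMM-scaled library sizes, ± SD over the 2 libraries, and log2 changes are given ± SE of the edgeR fit.

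The 20 gene lists were tested in each contrast with camera from limma 3.58.1 at a preset correlation of 0.01, and p-values were adjusted over the 100 tests. The same tests were run with an estimated correlation, given beside lists that passed, and with fry, given only as the number of tests that passed. Counts of list members past the test are given over all genes tested and adjusted over the list alone. Doxorubicin response sets held genes with a mean change over both genotypes of at least 1 on the log2 scale and an adjusted p under 0.05. The deposited TPM table was tested with limma on log2(TPM + 1), a scale that understates changes of low genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

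The groups, tests, contrasts, gene lists, the rule for named genes and the alternatives below other than the last 3 were fixed before the data were examined. Under that rule the text names genes from, for each contrast, the 8 largest rises and the 8 largest falls among genes past the test with a mean of at least 5 CPM, an official symbol and, for contrasts of 2 groups, no overlap between the libraries of the groups. It also draws on up to 4 members of each list with the smallest adjusted p, the BAF subunits, and genes of the deposited TPM table that belong to a list. Not every gene that met the rule is named. Results of 2 genes that met this rule are not reported here. Reads of FAM72B and FAM72D, of CYP4F2 and CYP4F3, and of the replication-dependent histones can be shared between near-identical copies, and most histone mRNAs lack the poly(A) tail that the kit selects, so their values are uncertain.

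Tested on simulated data with the real means and library sizes, the edgeR test recovered 82.1% of the 67 genes changed 2-fold in the contrast of doxorubicin in WT (17401 genes), 74.6% in R350H (17419), 80.6% for genotype untreated (17384), 76.1% for genotype with doxorubicin (17415) and 68.7% for the difference between responses (17410). Unchanged genes made up 14 of 175 calls for doxorubicin in WT and 4 of 156 in R350H. They made up 11 of 174 for genotype untreated, 11 of 161 for genotype with doxorubicin and 17 of 146 for the difference between responses. This share exceeded the adjusted p cutoff in every contrast except doxorubicin in R350H, and it was largest for the difference between responses. Far fewer genes were changed in the simulation than were called in the data, so these rates may not carry over. A planted shift of 40 genes by 1.5-fold was found by camera in each contrast, and 0 of 20 random sets passed. Simulated genes varied independently, so these results cannot vouch for the preset correlation in lists whose genes vary together. The limma test on simulated TPM recovered 56 of 58, 54 of 56, 54 of 60, 50 of 55 and 50 of 54 genes changed 2-fold, in the order of the contrasts above.

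The alternatives were RLE scaling, library size only, no filter, a filter of 50 counts in 2 libraries, an adjusted p under 0.01, a test against a 1.5-fold change, only the 4 libraries compared, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, other response sets, and other pseudocounts and filters for the TPM table. Fits without the 2 libraries of strand setting 1, without mitochondrial genes and without genes of 2 chromosome regions were added after seeing the data.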

Results

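The series asked how the R350H change in DPF2 alters gene expression when DNA is damaged. HCT116 is a line from a human colon carcinoma. DPF2 is a subunit of the BAF chromatin remodelling complex, and the study's design states that complexes with the R350H subunit interact poorly with nucleosomes that carry H3K56ac, an acetylated form of histone H3. Doxorubicin, a topoisomerase II poison that breaks DNA, was given at 0.5 µM for 24 h. The 4 groups of 2 libraries held 28111673 to 33727374 counts per library, and 17868 genes were tested. The first principal component (45.9% of the variance) separated treated from untreated libraries, and the second (33.0%) separated the genotypes. Log2 CPM values correlated at 0.992 to 0.995 across genes between the 2 libraries of a group. Mitochondrially encoded transcripts took 11.2 to 11.8% of the counts in untreated libraries and 13.5 to 14.6% after doxorubicin.

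DPF2 (ENSG00000133884.10, chromosome 11, 65333852 to 65354262, hg38) was counted at 94.7 and 92.7 CPM in untreated WT, 106 and 108 CPM in treated WT, 58.6 and 54.4 CPM in untreated R350H, and 54.3 and 53.5 CPM in treated R350H cells. It was lower in R350H by -0.73 ± 0.07 on the log2 scale untreated (edgeR adjusted p = 9.3e-10) and by -0.99 ± 0.07 with doxorubicin (edgeR adjusted p = 1.5e-12). The counts do not show which base stands at the edited codon. The 162 genes within 3 Mb of DPF2 had median differences of -0.09 and -0.08.

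In WT cells, doxorubicin raised most p53 target genes and lowered the genes of mitosis. TP53I3, an oxidoreductase gene induced by p53, rose from 16.3 ± 1.5 to 252.2 ± 0.4 CPM (15.5-fold, log2 change 3.96 ± 0.08, n = 2 per group). The polo-like kinase gene PLK2 rose by 3.08 ± 0.08, MDM2, which encodes the ubiquitin ligase of p53, by 2.09 ± 0.07, and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, by 1.88 ± 0.07. PLK1, a kinase needed for mitotic entry and spindle assembly, fell from 119.6 ± 4.7 to 17.32 ± 0.09 CPM (log2 change -2.79 ± 0.08). HMMR, a spindle factor, changed by -2.62 ± 0.08, CENPE, a kinetochore motor, by -2.69 ± 0.08, and CCNB1, cyclin B1, by -2.25 ± 0.07. Of 47 p53 targets, 42 rose and 1 fell (43 and 1 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 1.99e-68, adjusted p = 0.0503 with an estimated correlation). All 40 genes of the G2/M list fell, also adjusted over the list alone (40), with a median of -1.56 (camera adjusted p = 2.45e-108, adjusted p = 0.0115 with an estimated correlation).

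Among genes with a symbol and a mean of at least 5 CPM, the largest rises in WT cells with doxorubicin included SORCS2, a sorting receptor (5.65 ± 0.15), COL5A1, a fibrillar collagen (5.20 ± 0.26), PLA2G4D, a phospholipase (5.17 ± 0.19), and CYP4F2, a fatty acid hydroxylase (4.60 ± 0.13). PINCR, a long noncoding RNA, rose by 4.19 ± 0.18 and INPP5D, an inositol phosphatase, by 3.70 ± 0.12. The largest falls among such genes included PIF1, a DNA helicase (-4.30 ± 0.13), SPX, a peptide hormone gene (-3.56 ± 0.21), IL20RB, a cytokine receptor subunit (-3.48 ± 0.13), FAM72B (-2.80 ± 0.23) and DMGDH, a mitochondrial dehydrogenase (-2.77 ± 0.20). The edgeR test called 4301 genes higher and 4219 lower, of which 906 and 1051 changed at least 2-fold. Tested against a change of 1.5-fold, 976 and 817 genes passed.

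Most genes of DNA replication on the G1/S list rose with doxorubicin in WT cells. PCNA, the sliding clamp of DNA polymerases and itself a p53 target, rose by 1.79 ± 0.07, CCNE1, cyclin E1, by 1.25 ± 0.10, DTL, a ubiquitin ligase adaptor, by 1.07 ± 0.08, and MCM4, a subunit of the replicative helicase, by 0.86 ± 0.06. Of the 45 genes of the G1/S list, 29 rose and 1 fell (30 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 1.85e-07, adjusted p = 0.172 with an estimated correlation). Ribosome biogenesis genes rose in 28 of 35 cases and fell in 3 (the same 28 and 3 adjusted over the list alone, median 0.46, adjusted p = 0.194 with an estimated correlation), among them MYBBP1A, a nucleolar regulator (1.24 ± 0.07), and RCL1, a factor of ribosomal RNA cleavage (1.41 ± 0.08). Among 18 WNT targets, 13 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.50, adjusted p = 0.1 with an estimated correlation). Among them was DKK1, a secreted WNT antagonist (1.49 ± 0.07). Of 17 epithelial genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.64, adjusted p = 0.163 with an estimated correlation). Members included CA2, carbonic anhydrase 2, up by 2.62 ± 0.08 and the adhesion molecule gene CEACAM1 up by 3.66 ± 0.17 on the counts, against 0.38 in log2(TPM + 1) in the deposited TPM table. Cholesterol synthesis genes rose in 13 of 25 cases and fell in 3 (13 and 3 adjusted over the list alone, median 0.25, adjusted p = 0.227 with an estimated correlation). Hypoxia and glycolysis genes rose in 15 of 30 and fell in 3 (15 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.530 with an estimated correlation), led by the glucose transporter SLC2A1 (1.37 ± 0.07). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone, median 0.36, adjusted p = 0.467 with an estimated correlation).

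Most interferon-stimulated genes and most stress genes were lower in treated WT cells. SAMD9, an antiviral effector, changed by -1.39 ± 0.08, IFIH1, a sensor of double-stranded RNA, by -1.24 ± 0.10, and OAS3, an oligoadenylate synthetase, by -0.92 ± 0.07. Of 37 interferon-stimulated genes, 25 fell and 1 rose (25 and 1 adjusted over the list alone, median -0.79, camera adjusted p = 2.74e-07, adjusted p = 0.391 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, changed by -1.59 ± 0.07, TRIB3, a pseudokinase induced by ATF4, by -1.29 ± 0.07, and HYOU1, a chaperone of the endoplasmic reticulum, by -1.17 ± 0.07. Of 28 genes of the integrated stress and unfolded protein response, 19 fell and 1 rose (21 and 2 adjusted over the list alone, median -0.45, camera adjusted p = 6.65e-13, adjusted p = 0.172 with an estimated correlation). The other 9 lists did not pass camera. Their medians were 0.04 for homologous recombination (10 higher, 6 lower), -0.52 for histones (0 and 6) and 0.01 for NF-kB genes (8 and 5). They were 0.18 for immediate early genes (15 and 8), 0.09 for mesenchymal genes (4 and 3), -0.04 for BAF subunits (7 and 9), 0.01 for H3K56 acetylation factors (5 and 5) and -0.26 for MHC class I genes (1 and 13). Adjusted over the list alone, recombination had 11 and 7, NF-kB genes 9 and 5 and immediate early genes 15 and 9, and the others kept their counts. Blood cell markers were tested with only 3 genes, of which 2 rose, ITGAM, an integrin subunit, by 2.46 ± 0.27 and CORO1A, an actin regulator, by 1.16 ± 0.18. The NF-kB target ICAM1, an adhesion molecule gene, rose by 5.16 ± 0.28.

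**Figure D1:**
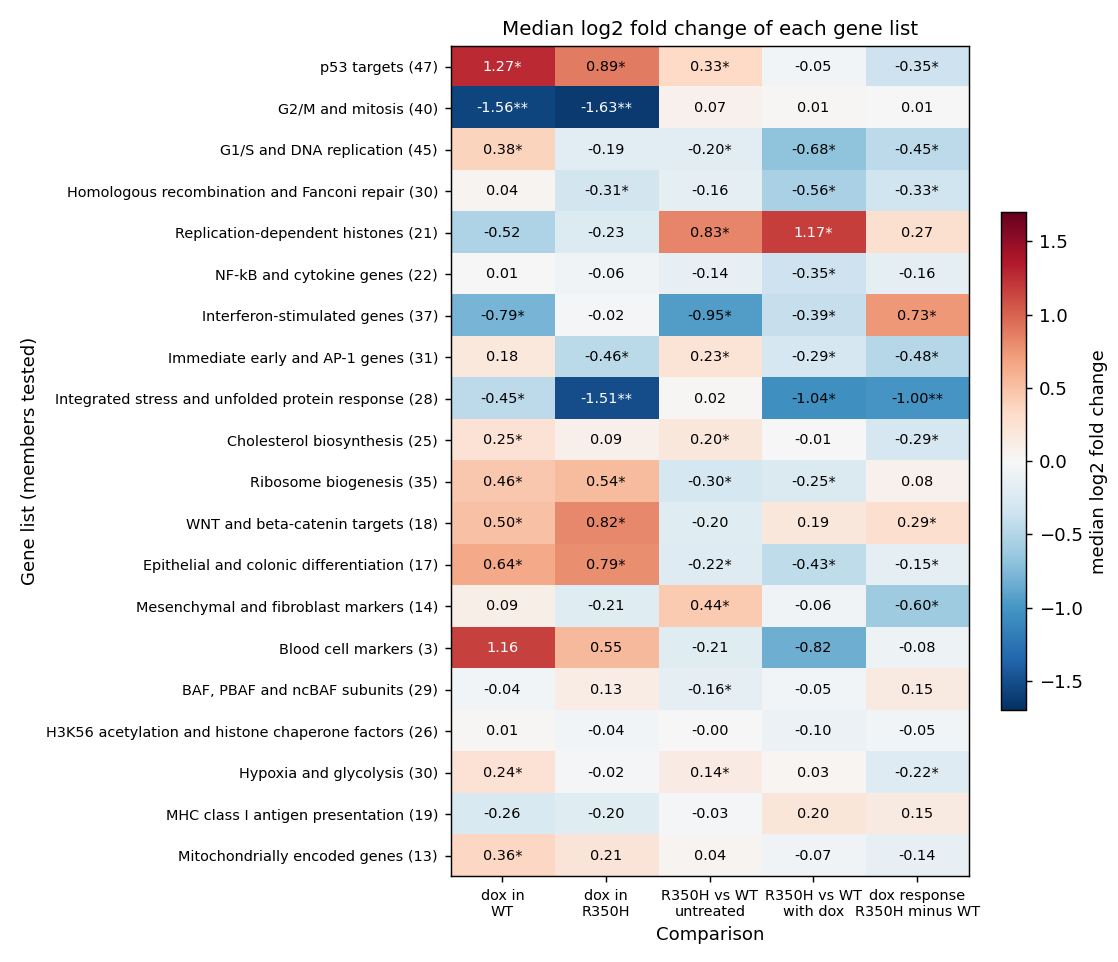
Median log2 fold change of the 20 gene lists (vertical axis, with the number of members tested) in the 5 comparisons (horizontal axis), with colour from blue (lower) to red (higher). A single asterisk marks a camera adjusted p under 0.05 and a double asterisk one that also held with an estimated correlation, as for the G2/M list, with medians of -1.56 in WT and -1.63 in R350H cells.

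In R350H cells, doxorubicin also raised most p53 targets and lowered mitotic genes, and it lowered genes of the integrated stress and unfolded protein response. DDIT3, the stress transcription factor CHOP, fell from 196.6 ± 7.9 to 14.22 ± 0.65 CPM (13.8-fold, log2 change -3.79 ± 0.08, n = 2 per group). SLC7A11, the cystine transporter, fell 15.9-fold (-3.99 ± 0.09), TRIB3 10.8-fold (-3.44 ± 0.08) and PHGDH 5.86-fold (-2.55 ± 0.07). PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate and is not on the list of stress genes, fell 12.7-fold (-3.67 ± 0.08). ASNS, asparagine synthetase, changed by -3.27 ± 0.10, CHAC1, a glutathione-degrading enzyme, by -3.26 ± 0.11, and ATF4, the transcription factor that drives many of these genes, by -1.63 ± 0.07. Of 28 genes of this list, 26 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -1.51 (camera adjusted p = 2.59e-74, adjusted p = 0.0352 with an estimated correlation).

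Of the 47 p53 targets, 39 rose and 6 fell in R350H cells (39 and 6 adjusted over the list alone, median 0.89, camera adjusted p = 1.89e-26, adjusted p = 0.0899 with an estimated correlation). TP53I3 rose by 3.21 ± 0.07, SESN1, a regulator of growth under stress, by 1.699 ± 0.08, MDM2 by 1.59 ± 0.07 and BAX, a mediator of apoptosis, by 1.43 ± 0.08. SESN2 (-1.26 ± 0.07) and GADD45A (-1.21 ± 0.07), 2 p53 targets that stress also induces, fell. All 40 mitotic genes fell, also adjusted over the list alone (40), with a median of -1.63 (camera adjusted p = 1.21e-94, adjusted p = 0.0115 with an estimated correlation), among them KIF2C, a microtubule depolymerase (-2.13 ± 0.07), and CDC20, an activator of the anaphase-promoting complex (-1.97 ± 0.07). BRCA1, which acts in homologous recombination, changed by -1.52 ± 0.07 and BRCA2 by -0.87 ± 0.09. Of the 30 genes of recombination and Fanconi repair, 17 fell and 4 rose (17 and 4 adjusted over the list alone, median -0.31, adjusted p = 0.194 with an estimated correlation). The immediate early genes ATF3 (-2.08 ± 0.08), JUN (-2.02 ± 0.08) and the phosphatase gene DUSP5 (-1.99 ± 0.07) were among 18 of 31 that fell, against 6 that rose (19 and 6 adjusted over the list alone, median -0.46, adjusted p = 0.312 with an estimated correlation).

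WNT targets rose in 15 of 18 cases and fell in 0 in R350H cells with doxorubicin (15 and 0 adjusted over the list alone, median 0.82, adjusted p = 0.0799 with an estimated correlation), among them the growth factor gene BMP4 (1.64 ± 0.07) and CCND1, cyclin D1 (1.05 ± 0.07). Ribosome biogenesis genes rose in 29 of 35 and fell in 2 (29 and 2 adjusted over the list alone, median 0.54, adjusted p = 0.194 with an estimated correlation). Epithelial genes rose in 10 of 17 and fell in 2 (11 and 4 adjusted over the list alone, median 0.79, adjusted p = 0.237 with an estimated correlation). Members included the water channel gene AQP3 up by 1.94 ± 0.10. The other 12 lists did not pass camera. G1/S genes had a median of -0.19 with 9 higher and 24 lower, interferon-stimulated genes -0.02 (4 and 6), histones -0.23 (1 and 2), NF-kB genes -0.06 (6 and 7). Cholesterol genes had a median of 0.09 (6 and 3), mesenchymal genes -0.21 (3 and 5), blood markers 0.55 (2 and 0), BAF subunits 0.13 (12 and 5), H3K56 factors -0.04 (6 and 7), hypoxia genes -0.02 (7 and 7), MHC class I genes -0.20 (6 and 9) and mitochondrially encoded genes 0.21 (9 and 0). Adjusted over the list alone, the counts were 3 and 6 for interferon-stimulated genes, 1 and 0 for histones, 7 and 7 for NF-kB genes, 12 and 6 for BAF subunits, 7 and 10 for MHC class I and 10 and 0 for mitochondrially encoded genes. For hypoxia the test pointed upward against a negative median and mean, and for MHC class I the mean was 0.001 against a negative median. VIM, the intermediate filament vimentin, changed by -3.20 ± 0.17. Among genes with a symbol and a mean of at least 5 CPM, COL5A1 (3.83 ± 0.22), SORCS2 (3.56 ± 0.16), PLA2G4D (3.41 ± 0.17) and the antisense RNA RNF157-AS1 (3.06 ± 0.25) were among the largest rises in R350H cells. The largest falls outside the lists among such genes were in SPX (-6.46 ± 0.29), IL20RB (-5.40 ± 0.15), LURAP1L (-4.41 ± 0.14), PCK2 (given above) and TSC22D3, a glucocorticoid-induced leucine zipper gene (-3.63 ± 0.10). The edgeR test called 4667 genes higher and 3889 lower, with 766 and 1033 past 2-fold. Against a change of 1.5-fold, 836 and 989 passed. All groups shared the fitted spread, though R350H libraries agreed more closely within a group than WT libraries. Fitted on only the 4 libraries compared, 4003 genes were higher and 3400 lower in WT, against 5064 and 4958 in R350H. How the number of calls compares between genotypes therefore depends on the shared spread.

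Both genotypes shared 3139 genes raised by doxorubicin, where independent lists would share 1123.4, and 2526 lowered genes, where they would share 918.3. Another 127 genes rose in WT and fell in R350H, and 97 did the opposite. Fold changes of the 2 genotypes, which share no libraries, correlated across genes at r = 0.708 and rho = 0.676, and genes are not independent replicates.

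**Figure D2:**
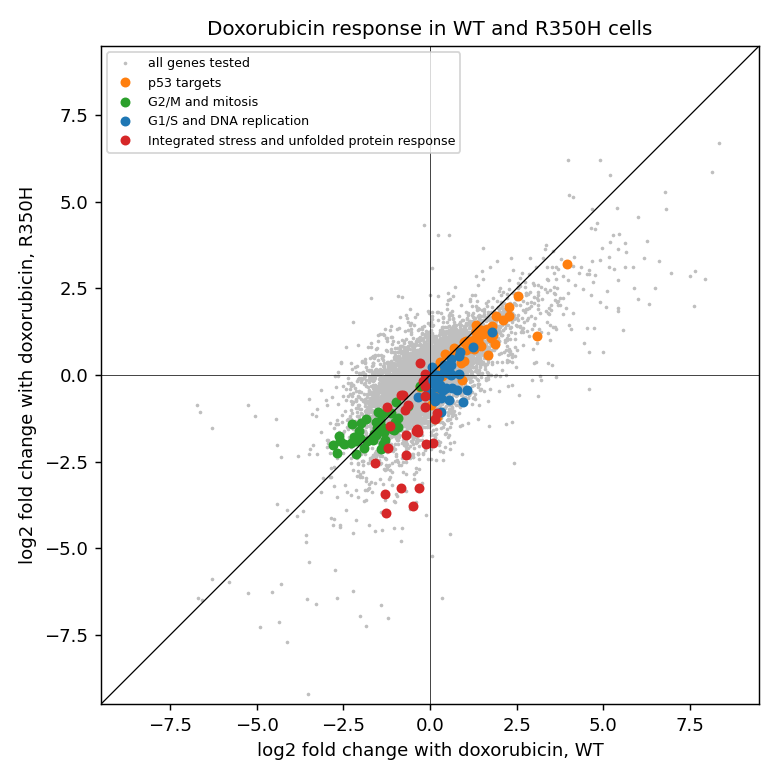
Log2 fold change with doxorubicin in WT (horizontal axis) and R350H cells (vertical axis), with 1 point per gene, 17868 in all, and 4 lists in colour. Stress genes (red) had medians of -0.45 in WT and -1.51 in R350H, with 19 of 28 called lower in R350H against the diagonal of equal response and 2 called higher.

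The doxorubicin response itself was then compared between the genotypes. By camera it was lower in R350H for stress genes, for p53 targets, for genes of DNA replication and repair and for immediate early genes, and higher for interferon-stimulated genes. Only the stress list held with an estimated correlation (camera adjusted p = 0.0352), and the others had camera adjusted p = 0.103 for p53 targets, 0.0503 for G1/S genes, 0.0899 for recombination, 0.1 for immediate early genes and 0.326 for interferon-stimulated genes. DDIT3 fell from 118.6 ± 9.6 to 84.81 ± 0.07 CPM in WT and from 196.6 ± 7.9 to 14.22 ± 0.65 CPM in R350H, a difference between responses of -3.31 ± 0.10 on the log2 scale (edgeR adjusted p = 2.14e-18). The differences were -2.93 ± 0.13 for CHAC1 and -2.71 ± 0.11 for SLC7A11, and outside the stress list -2.64 ± 0.10 for PCK2 and -2.52 ± 0.11 for ATF3. Of 28 stress genes, 19 had a lower and 2 a higher response in R350H (20 and 3 adjusted over the list alone), with a median of -1.001 (camera adjusted p = 3.98e-84, adjusted p = 0.0352 with an estimated correlation).

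**Figure D3:**
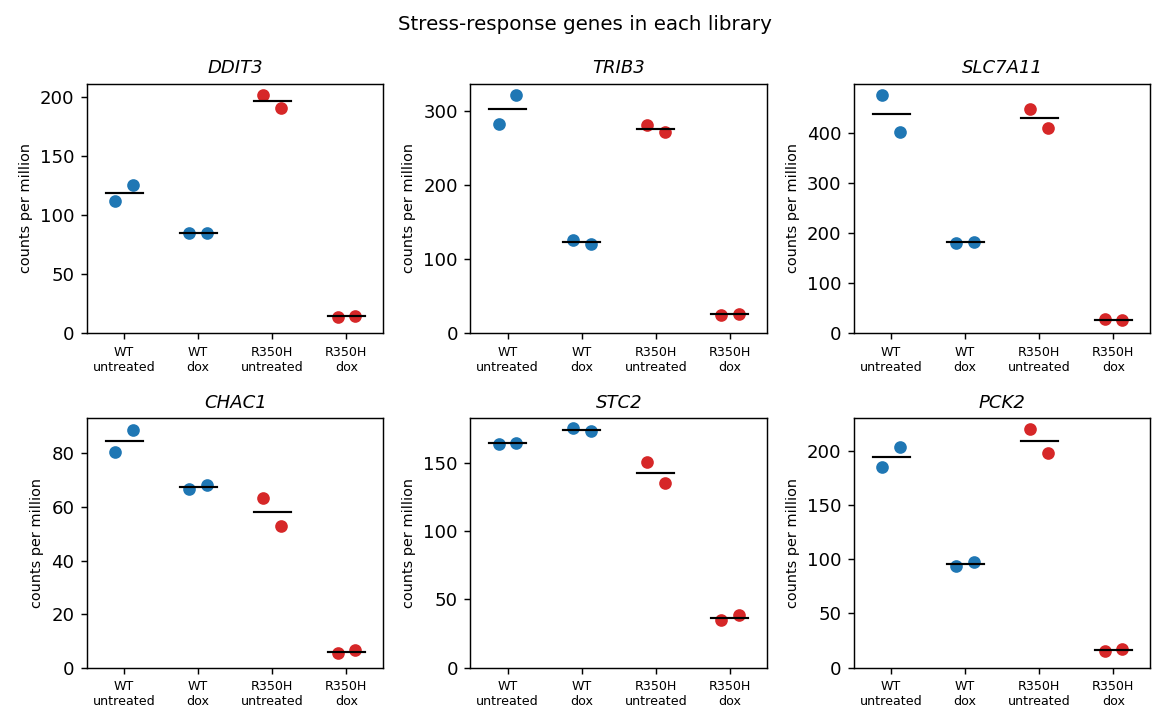
CPM of 6 genes in the 8 libraries, all on the stress list except PCK2, with 1 point per library, lines at the group means, WT in blue and R350H in red. Each of the 6 genes was lowest in the treated R350H libraries, where DDIT3 stood at 14.22 CPM.

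For p53 targets, 26 of 47 had a lower response in R350H and 0 a higher one (30 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 6.08e-22, adjusted p = 0.103 with an estimated correlation). Members included PLK2 at -1.96 ± 0.11 and SESN2 at -1.42 ± 0.10. Untreated R350H cells already had more of 31 of these 47 transcripts and less of 0 (median 0.33). After doxorubicin the list stood near the WT level (median -0.05, 11 higher and 14 lower). For G1/S genes the numbers were 27 and 0 of 45 (30 and 0 adjusted over the list alone, median -0.45, adjusted p = 0.0503 with an estimated correlation). Members included RRM2, a subunit of ribonucleotide reductase, at -1.37 ± 0.10 and CDC6, a licensing factor of replication origins, at -1.25 ± 0.09. RRM2 rose by 0.31 ± 0.07 in WT and changed by -1.06 ± 0.07 in R350H. For recombination and Fanconi genes, 14 of 30 were lower and 0 higher (15 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.0899 with an estimated correlation). Members included BRCA1 at -1.08 ± 0.10 and FANCI, a Fanconi complex member, at -0.86 ± 0.09. Immediate early genes were lower in 19 of 31 cases and higher in 1 (21 and 1 adjusted over the list alone, median -0.48, adjusted p = 0.1 with an estimated correlation). Members included DUSP5 at -1.96 ± 0.10. Interferon-stimulated genes had a higher response in 13 of 37 cases and a lower one in 1 (15 and 2 adjusted over the list alone, median 0.73, adjusted p = 0.326 with an estimated correlation). Members included the ADP-ribosyltransferase gene PARP9 at 0.97 ± 0.11 and OAS3 at 0.95 ± 0.10. Untreated R350H cells already had less of both transcripts.

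Among the other lists past camera, cholesterol genes had a lower response in 10 of 25 cases and a higher one in 2 (12 and 2 adjusted over the list alone, median -0.29, adjusted p = 0.194 with an estimated correlation). Members included STARD4, a sterol transporter, at -0.98 ± 0.11. WNT targets were higher in 6 of 18 and lower in 3 (8 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.312 with an estimated correlation). Members included BMP4 at 0.98 ± 0.09 and the transcription factor gene SOX4 at 0.63 ± 0.10. Hypoxia genes were lower in 7 of 30 and higher in 0 (9 and 0 adjusted over the list alone, median -0.22, adjusted p = 0.386 with an estimated correlation). Members included HK2, hexokinase 2, at -1.06 ± 0.10 and the stress gene NDRG1 at -0.85 ± 0.10. Mesenchymal genes were lower in 6 of 14 and higher in 2 (6 and 2 adjusted over the list alone, median -0.60, adjusted p = 0.217 with an estimated correlation). Members included S100A4, a calcium-binding protein gene, at -0.76 ± 0.11 and ACTA2, smooth muscle actin, at -0.74 ± 0.15. Epithelial genes were lower in 3 of 17 and higher in 2 (5 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.432 with an estimated correlation). Members included CA2 at -1.38 ± 0.12 and CEACAM1 at -1.56 ± 0.24. For CEACAM1 the deposited TPM table gave 0.09 in log2(TPM + 1) (limma adjusted p = 0.637). That scale understates changes of low genes, so the TPM value neither bears out nor contradicts the count value. The medians of lists that did not pass camera were 0.01 for G2/M (12 higher, 9 lower), 0.27 for histones (0 and 0), -0.16 for NF-kB genes (1 and 5). They were 0.08 for ribosome biogenesis (3 and 2), -0.08 for blood markers (0 and 0), 0.15 for BAF subunits (5 and 1), -0.05 for H3K56 factors (1 and 5), 0.15 for MHC class I (3 and 0) and -0.14 for mitochondrially encoded genes (0 and 0). Adjusted over the list alone, G2/M had 14 higher and 10 lower, NF-kB genes 1 and 6, BAF subunits 6 and 2 and H3K56 factors 3 and 7.

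With a symbol and a mean of at least 5 CPM, the genes with the largest differences upward were PIF1 (1.92 ± 0.18), the antisense RNA SLC16A4-AS1 (1.90 ± 0.25), SAMD11 (1.35 ± 0.26) and SEMA3A, an axon guidance factor (1.34 ± 0.29). Downward outside the lists they were LURAP1L (-3.37 ± 0.17), SPX (-2.91 ± 0.50), PCK2 (-2.64) and TSC22D3 (-2.60 ± 0.12). The edgeR test called 1155 genes with a higher and 1462 with a lower response in R350H, 111 and 283 of them past 2-fold. Of the genes with a lower response, 380 fell in R350H only by the single tests, 351 fell in both genotypes and 305 rose only in WT. Another 284 rose in both and 127 rose in WT and fell in R350H. Which genes count as called in only 1 genotype depends on the spread shared by all groups. Higher and lower calls were both fewer than in the main fit whichever R350H library was left out, so the drop does not point to a single library. R350H libraries agreed more closely within a group than WT libraries, and whether the shared spread caused the drop was not tested. The number of lower calls was not stable either, and it was largest without treated WT replicate 2. Higher calls made up 44.1% of the total with TMM, 33.9% with RLE and 59.0% with library size only, so the balance of directions depended on scaling. For 811 genes that doxorubicin raised on average over both genotypes, the median response was 1.68 in WT and 1.37 in R350H, a median difference of -0.35, and 573 of them (70.7%) responded less in R350H (camera p = 2.82e-07, p = 0.0225 with an estimated correlation). The difference depended on the set: it was -0.09 for genes with a mean log2 change of at least 0.58, -0.53 for genes chosen on WT alone and 0.0071 for genes chosen on R350H alone, where the call was lost. Over the alternatives the camera p ran from 3.55e-18 to 0.531. For 1057 lowered genes the median difference was -0.06 (camera p = 5.26e-05, p = 0.0151 with an estimated correlation), and it was 0.01 without untreated WT replicate 2 and 0.21 without treated WT replicate 2, where the call was lost. It was 0.51 for lowered genes chosen on WT alone and -0.55 for those chosen on R350H alone.

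Before treatment, R350H cells had less of most interferon-stimulated transcripts and more of several p53 targets than WT cells. PARP9 was lower by -1.14 ± 0.08, IFIH1 by -1.31 ± 0.10, DTX3L, a partner of PARP9, by -1.05 ± 0.08 and IFIT2, an antiviral effector, by -1.49 ± 0.12. Of 37 interferon-stimulated genes, 32 were lower and 0 higher (34 and 0 adjusted over the list alone, median -0.95, camera adjusted p = 2.74e-18, adjusted p = 0.194 with an estimated correlation). PLK2 was higher by 1.19 ± 0.08, CDKN1A by 0.90 ± 0.07 and BTG2, an antiproliferative gene, by 0.88 ± 0.07. Of 47 p53 targets, 31 were higher and 0 lower (33 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 1.27e-11, adjusted p = 0.194 with an estimated correlation).

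The immediate early genes EGR1 (1.102 ± 0.07) and JUN (1.04 ± 0.07), both transcription factors, were higher in untreated R350H cells, as were 16 of 31 on that list, against 5 lower (16 and 5 adjusted over the list alone, median 0.23, adjusted p = 0.451 with an estimated correlation). Histone genes were higher in 12 of 21 cases and lower in 0 (12 and 0 adjusted over the list alone, median 0.83, adjusted p = 0.0899 with an estimated correlation), with the uncertainty of shared reads. Cholesterol genes were higher in 12 of 25 and lower in 2 (13 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.194 with an estimated correlation). Members included HMGCS1, an early enzyme of the pathway, at 0.88 ± 0.07, which lies in a region of chromosome 5 where the median gene was higher by 0.83. VIM (2.12 ± 0.15) and the collagen gene COL6A3 (1.68 ± 0.12) were among 7 of 14 mesenchymal genes that were higher, against 2 lower (8 and 2 adjusted over the list alone, median 0.44, adjusted p = 0.194 with an estimated correlation). SPARC, a matrix protein gene, was lower by -2.70 ± 0.29. Hypoxia genes were higher in 13 of 30 and lower in 4 (13 and 4 adjusted over the list alone, median 0.14, adjusted p = 0.640 with an estimated correlation). Members included the pyruvate kinase gene PKM at 0.81 ± 0.07. MCM2, a helicase subunit, was lower by -0.87 ± 0.07 as part of 19 lower and 5 higher of 45 G1/S genes (19 and 5 adjusted over the list alone, median -0.20, adjusted p = 0.425 with an estimated correlation). Ribosome biogenesis genes were lower in 25 of 35 and higher in 0 (25 and 1 adjusted over the list alone, median -0.30, adjusted p = 0.237 with an estimated correlation). Members included NOP14 at -0.66 ± 0.06. Epithelial genes were lower in 9 of 17 and higher in 2 (9 and 2 adjusted over the list alone, median -0.22, adjusted p = 0.391 with an estimated correlation). Members included the transcription factor gene ELF3 at -1.10 ± 0.07. BAF subunits were lower in 14 of 29 cases and higher in 2 (14 and 2 adjusted over the list alone, median -0.16, adjusted p = 0.194 with an estimated correlation). Besides DPF2, these included the core subunits SMARCC1 (-0.77 ± 0.07) and SMARCC2 (-0.62 ± 0.06) and the ATPase SMARCA4 (-0.54 ± 0.06), while BRD9, a subunit of the noncanonical complex, was higher (0.60 ± 0.07).

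The largest difference among genes with a symbol and a mean of at least 5 CPM was in ZNF84, a zinc finger gene (chromosome 12, 133037292 to 133063304), counted at 21.59 ± 0.25 CPM in untreated WT and at 0 in both untreated R350H libraries, at least 463-fold lower with a floor of 3 counts over the group. PDE4B, a cyclic AMP phosphodiesterase (-7.01 ± 0.19), ABCA1, a cholesterol exporter (-6.29 ± 0.28), and SEMA3A (-5.53 ± 0.18) were also far lower. GCHFR, a regulator of GTP cyclohydrolase (5.64 ± 0.26), FSTL4 (5.50 ± 0.23), TIMP3, an inhibitor of matrix proteases (4.34 ± 0.15), and ALDH1L1, a folate enzyme (3.27 ± 0.07), were higher. The edgeR test called 3084 genes higher and 3486 lower, with 536 and 499 past 2-fold. Higher calls made up 46.9% with TMM and 57.4% with library size only. The lists that did not pass camera had medians of 0.07 for G2/M (12 higher, 6 lower), -0.16 for recombination (6 and 12), -0.14 for NF-kB genes (2 and 5), 0.02 for stress genes (8 and 7). WNT targets stood at -0.20 (7 and 8), with -0.21 for blood markers (0 and 1), -0.005 for H3K56 factors (3 and 6), -0.03 for MHC class I (2 and 2) and 0.04 for mitochondrially encoded genes (4 and 0). G2/M had 14 and 6 adjusted over the list alone, stress genes 9 and 8 and WNT targets 7 and 9.

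Expression also differed by chromosome region between the lines. Of 94 genes of chromosome 5 before 50 Mb with at least 2 CPM, 83 were higher in R350H in both treatments, with medians of 0.83 untreated and 0.88 with doxorubicin. Of 206 genes of chromosome 8 after 90 Mb, 139 were lower in both, with medians of -0.57 and -0.52. Genes of other chromosomes (11893) had medians of -0.02 and -0.01. BRD9 and HMGCS1, whose values are given above, lie in the first region, and NDRG1, MYC, SQLE, BOP1 and TONSL lie in the second. These regions were singled out after their values were seen.

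**Figure D4:**
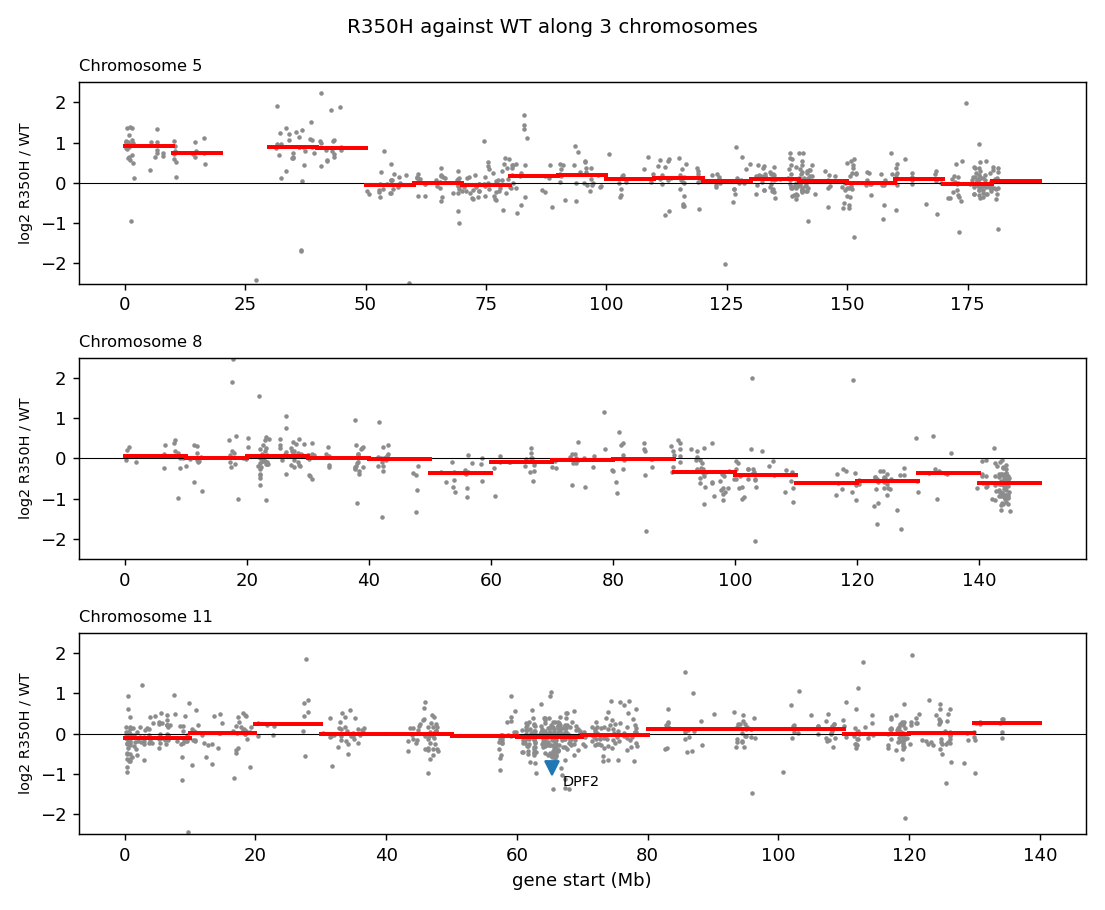
Log2 R350H over WT, averaged over both treatments (vertical axis), for genes with at least 2 CPM along chromosomes 5, 8 and 11 (horizontal axis, Mb), with red lines at medians of windows that held at least 10 genes and a triangle at DPF2. Windows before 50 Mb of chromosome 5 stood at 0.74 to 0.92 and those after 90 Mb of chromosome 8 at -0.62 to -0.34, and 1 gene of chromosome 5 lies outside the axis of 2.5.

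After doxorubicin, R350H cells had less transcript than WT cells from most stress genes and most genes of DNA replication and repair on the lists. CHAC1 was lower by -3.47 ± 0.11, SLC7A11 by -2.74 ± 0.09, DDIT3 by -2.58 ± 0.08, TRIB3 by -2.27 ± 0.08 and STC2, a secreted glycoprotein gene induced by stress, by -2.24 ± 0.07. Of 28 stress genes, 19 were lower and 5 higher (19 and 5 adjusted over the list alone, median -1.04, camera adjusted p = 2.25e-43, adjusted p = 0.0503 with an estimated correlation). DTL was lower by -1.50 ± 0.08, CDC6 by -1.13 ± 0.07 and RRM2 by -1.04 ± 0.07, and 42 of 45 G1/S genes were lower and 0 higher (42 and 0 adjusted over the list alone, median -0.68, camera adjusted p = 4.39e-24, adjusted p = 0.0503 with an estimated correlation). Of 30 recombination and Fanconi genes, 26 were lower and 1 higher (26 and 1 adjusted over the list alone, median -0.56, adjusted p = 0.103 with an estimated correlation). Members included BRCA1 at -0.90 ± 0.07 and FANCI at -0.83 ± 0.06.

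Immediate early genes were lower in 19 of 31 cases and higher in 3 in treated R350H cells (19 and 3 adjusted over the list alone, median -0.29, adjusted p = 0.326 with an estimated correlation). Members included DUSP5 at -2.08 ± 0.07 and ATF3 at -1.95 ± 0.08. NF-kB genes were lower in 12 of 22 and higher in 0 (12 and 0 adjusted over the list alone, median -0.35, adjusted p = 0.194 with an estimated correlation). Members included ICAM1 at -2.59 ± 0.20. Interferon-stimulated genes were lower in 17 of 37 and higher in 6 (19 and 6 adjusted over the list alone, median -0.39, adjusted p = 0.646 with an estimated correlation). Members included OASL at -1.78 ± 0.13 and SAMD9 at 0.76 ± 0.08. Histone genes were higher in 14 of 21 and lower in 0 (14 and 0 adjusted over the list alone, median 1.17, adjusted p = 0.0799 with an estimated correlation). Ribosome biogenesis genes were lower in 23 of 35 and higher in 1 (23 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.312 with an estimated correlation). Members included FBL, the fibrillarin methyltransferase, at -0.72 ± 0.07. Epithelial genes were lower in 10 of 17 and higher in 1 (11 and 1 adjusted over the list alone, median -0.43, adjusted p = 0.194 with an estimated correlation). Members included CA2 at -2.501 ± 0.08. The p53 targets went both ways (11 higher, 14 lower, median -0.05). CDKN1A stood at -0.08 ± 0.07 (edgeR adjusted p = 0.376), while SESN2 was lower by -1.17 ± 0.07. The remaining lists had medians of 0.01 for G2/M (15 and 9), -0.01 for cholesterol genes (7 and 5), 0.19 for WNT targets (8 and 5), -0.06 for mesenchymal genes (4 and 5), -0.82 for blood markers (0 and 2). They were -0.05 for BAF subunits (2 and 8), -0.10 for H3K56 factors (3 and 9), 0.03 for hypoxia genes (8 and 7), 0.20 for MHC class I (7 and 1) and -0.07 for mitochondrially encoded genes (2 and 3), and none passed camera. G2/M had 16 and 9 adjusted over the list alone, cholesterol genes 7 and 6 and MHC class I genes 9 and 1. For hypoxia the mean and the test were negative against a positive median, and for cholesterol genes the mean and the test were positive against a negative median.

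ZNF84 was counted at 16.6 ± 1.6 CPM in treated WT and at 0 in both treated R350H libraries, at least 360-fold lower. PDE4B (-6.92 ± 0.17), ZNF211 (-6.13 ± 0.24), ABCA1 (-6.05 ± 0.20), FSTL4 (5.31 ± 0.18) and GCHFR (4.39 ± 0.21) differed far more than most genes here too. The edgeR test called 3421 genes higher and 3751 lower, with 704 and 707 past 2-fold. The higher calls numbered 1987 without treated R350H replicate 1 and 2133 without replicate 2, and higher calls made up 47.7% with TMM and 66.1% with library size only, a scaling that moved the median of all genes to 0.11. Without genes of the regions on chromosomes 5 and 8, 3263 genes were higher and 3596 lower. Both treatments shared 1696 genes higher in R350H, where independent lists would share 590.5, and 2116 lower genes, where they would share 731.8. Another 224 were higher untreated and lower with doxorubicin, and 79 the opposite.

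The deposited TPM table held a selection of genes, 14 of them on the stress list and 6 on the p53 list. On log2(TPM + 1), limma called 2 genes with a higher and 184 with a lower doxorubicin response in R350H, and on the counts of the same genes edgeR called 0 and 201. The genes were therefore treated as chosen on these samples, and their direction is not independent evidence. With doxorubicin limma called 83 higher and 75 lower in WT and 31 and 144 in R350H, and between genotypes 94 higher and 37 lower untreated and 9 and 150 after treatment. Among 185 genes called by both tests for the response, 183 had the same direction, and ARG2 and L3MBTL2-AS1 did not. The sizes differed, with r = 0.351 between the log2 differences of the 2 tables for the response and 0.729 to 0.857 for the other contrasts. Of the gene values called on the counts and printed above, limma on TPM did not call CEACAM1 (0.09, adjusted p = 0.637) or SPX (-0.32, adjusted p = 0.0642) for the response, SORCS2 with doxorubicin in R350H (0.12, adjusted p = 0.0556), RRM2 with doxorubicin in WT (0.01, adjusted p = 0.901) or BRCA1 between treated genotypes (-0.16, adjusted p = 0.103).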

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

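The 4 tests of explanations for the stress genes were chosen after the result was seen, while the tests of the single genes and lists were planned. Each value here stands because a test of the difference between the doxorubicin responses of R350H and WT cells passed its threshold. The response was higher in R350H for 1155 genes and lower for 1462. A higher response can be a smaller fall, as for PIF1, as well as a larger rise. Its median difference was -0.35 for genes raised by doxorubicin and -0.058 for lowered genes. Medians of lists were -0.35 for p53 targets, -0.45 for G1/S genes, -0.33 for recombination and Fanconi genes, 0.73 for interferon-stimulated genes, -0.48 for immediate early genes, -1.001 for stress genes, -0.29 for cholesterol genes, 0.29 for WNT targets, -0.15 for epithelial genes, -0.60 for mesenchymal genes and -0.22 for hypoxia genes. With an estimated correlation only the stress list held (camera adjusted p = 0.0352), and the other 10 lists lost the call, at camera adjusted p = 0.0503 to 0.432.

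Single genes with a higher response in R350H were PIF1 (1.92), SLC16A4-AS1 (1.90), SAMD11 (1.35), SEMA3A (1.34), GATA2-AS1 (1.22), LINC01355 (1.202), ZNF469 (1.15), PURPL (1.14), BMP4 (0.98), PARP9 (0.97), OAS3 (0.95) and SOX4 (0.63). Stress genes and their neighbours in size with a lower response were LURAP1L (-3.37), DDIT3 (-3.31), CHAC1 (-2.93), SPX (-2.91), SLC7A11 (-2.71), PCK2 (-2.64), TSC22D3 (-2.60) and ATF3 (-2.52). Further genes with a lower response were DUSP5 (-1.96), PLK2 (-1.96), CEACAM1 (-1.56), SESN2 (-1.42), CA2 (-1.38), RRM2 (-1.37) and CDC6 (-1.25). So were BRCA1 (-1.08), HK2 (-1.06), STARD4 (-0.98), FANCI (-0.86), NDRG1 (-0.85), S100A4 (-0.76) and ACTA2 (-0.74). For CEACAM1 the deposited TPM table gave 0.09 on the unlike scale of log2(TPM + 1) (limma adjusted p = 0.637), which does not bear out the count value or contradict it.

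Scaling is argued against as the cause of the larger fall of stress genes in R350H by the median response difference, which was -0.94 at its highest under TMM, RLE and library size only. A smaller doxorubicin response overall would bring the list nearer 0 in R350H, so the pattern itself argues against it (list median -1.51 in R350H against -0.45 in WT), and G2/M genes fell as far in R350H (-1.63 against -1.56). Copy number of the shifted regions of chromosomes 5 and 8 cannot act on the genes themselves, since 0 of the 28 members lie there (median response difference -1.001), though a regulator could. Culture conditions shared by both treated R350H libraries cannot be told apart from the genotype, because their list medians differed by only 0.0068 and any cause acting on the whole group would give that. The R350H change in DPF2 and another difference between the lines therefore stay open, as hypotheses.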

How the results depend on the processing

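Fits without the libraries of strand setting 1, without mitochondrial genes and without the 2 chromosome regions were chosen after seeing the data. The other alternatives were planned. Named genes were rerun only with RLE, DESeq2, the replicate block, only the 4 libraries compared and each library left out. Lists were rerun only with RLE and the replicate block, and on the main fit with an estimated correlation and fry. Many named genes were picked for their result in the main fit, so few reversals could arise among them. Of the values of named genes under the alternatives, 8054 kept direction and side of the threshold, 259 kept direction but lost the call, 30 gained it and 0 reversed; for lists the numbers were 327, 48, 25 and 0. Against a 1.5-fold change, 976 higher and 817 lower genes passed for doxorubicin in WT, 836 and 989 in R350H, 427 and 471 for genotype untreated, 492 and 736 for genotype with doxorubicin, and 21 and 206 for the difference between responses, since this test asks for more. At an adjusted p under 0.01, the response difference kept 464 higher and 911 lower genes. Library size only gave 5157 higher genes for genotype with doxorubicin. DESeq2 gave 2279 there and 557 for a higher response; the cause was not tested. Without the libraries of strand setting 1, there were 1930 higher genes for genotype untreated and 720 for a higher response. Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 417 to 1219 genes with a higher response and 1987 to 3620 higher for genotype with doxorubicin, and the median of lowered genes ran from -0.21 to 0.21, reversing to 0.01 without untreated WT replicate 2 and to 0.21 without treated WT replicate 2; the cause was not tested. A mean log2 change of at least 0.58 gave a median of -0.09 for raised genes. The median of lowered genes, -0.058 in the main fit, was -0.014 at that cutoff, -0.0016 with library size only and -0.17 with the filter of 50 counts. Sets chosen on 1 genotype reversed medians to 0.51 (lowered, chosen on WT) and 0.0071 (raised, chosen on R350H), a choice that by construction favours a larger response in that genotype. Of the 100 list tests, 50 passed with the preset correlation, 4 with an estimated correlation and 74 with fry, which does not compare a list with other genes. In the TPM table a pseudocount of 0.1 left 1 gene with a higher response in place of 2. Replicates share only a number: with the replicate block, 1090 genes had a higher and 1405 a lower response, no other count moved by over 1.5 times, list calls did not change, and same-numbered libraries deviated together at correlations of -0.08 to 0.04. At these depths and with 2 libraries per group, the simulated test recovered 46.3% of genes with a 1.5-fold difference between responses. The data had many more genes called for this contrast (14.6%) than the simulation had changed, so recovery in the data may differ. Depth was not varied, so its share in this limit is open.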

Other observations

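All 5 tests of explanations for the ribosomal protein genes and both tests for the chromosome regions were chosen after the result was seen. Genes of ribosomal proteins, a group not on any list fixed earlier and singled out after its values were seen, were lower in R350H cells. Of 81 such genes, 72 were lower and 1 higher untreated, with a median of -0.47, and 75 were lower and 1 higher with doxorubicin, with a median of -0.50 (camera p = 1.86e-25 and 7.01e-23, p = 0.144 and 0.162 with an estimated correlation). Doxorubicin itself left medians of -0.09 in WT and -0.11 in R350H. Ribosome biogenesis genes, which make and assemble ribosomal RNA, had genotype medians of -0.30 and -0.25.

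Scaling is argued against as the cause of the lower ribosomal protein transcripts, since the highest of 6 medians over 3 scalings and 2 treatments was -0.38. The regions of chromosomes 5 and 8 hold 3 of the genes, and the others had a median of -0.48, which argues against regional copy number. A loss of short or abundant transcripts could lower such genes: genes matched on exon length over all transcripts and on level had a median of -0.11, which decided nothing, so the match was changed to the length of the principal transcript and split by treatment. It then gave 0.12 ± 0.04 untreated (SE by resampling genes), which argues against that loss, and -0.14 ± 0.07 with doxorubicin, which does not decide. The matched genes were longer (a median of 1021 against 709 bases), and with the estimated correlation the group's own call was lost, so a difference between the lines stays a hypothesis.

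The shifts along chromosomes 5 and 8 were weighed between DNA copy number and the strand setting. Strand setting is argued against, because between the treated libraries, all counted with setting 2, the smaller of the 2 shifts was -0.52. Copy number that differs between the lines was not contradicted by its test. Genes above and below the median level of a region shifted alike, with medians at most 0.10 apart. Doxorubicin medians in the regions lay between 0.02 and 0.12. Chromosome 5 after 50 Mb, which was not shifted, passed as well (0.02 and 0.07, with doxorubicin medians of -0.07 and -0.03). The test therefore does not tell copy number from another cause that acts on a whole region. Of 288 windows of the genome, 275 of the 278 outside the regions lay within 0.3 of 0, and the other 3 stood at 0.49 (chromosome 3, 90 to 100 Mb), -0.36 (chromosome 8, 50 to 60 Mb) and 0.302 (chromosome 2, 140 to 150 Mb), so the shift may not be confined to the 2 regions. Copy number was not measured, and a gain or loss in the R350H line, in the WT line or in a clone during editing remain candidate explanations that the RNA cannot separate.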
